A study of Mus musculus with 6 samples.

How the data were processed

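The material was mouse colonic mucosa, scraped off with a microscope slide and frozen, from Tlr2 knockout and wild-type C57BL/6 mice at 90 postnatal days, per the labels' protocols. RNA of 4 sample pairs was labelled for expression arrays and digested, amplified DNA of 2 of these knockout samples with their wild-type partners for methylation arrays. Each sample's group, pair number and dye were taken from the labels, and every ratio was turned to knockout over wild type.

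The scanner files hold spot intensity per channel, as median pixel signals, local background and processed signals made with Agilent Feature Extraction, per the file headers. The version is 10.5.1.1 per the file headers and 8.5.1.1 per the submitters' processing notes, and this difference was not resolved. The processed intensity was background subtracted and scaled with 1 linear dye factor per channel, per the file headers. The log10 ratio of Cy5 over Cy3 that the authors deposited in the same files was compared with the processed signals and not used further. The authors deposited 4 tables of hits with a linear ratio of knockout over wild type per array and its average, per the file headers. Per the series' design text, a transcript was kept when it changed over 1.6-fold on at least 2 arrays and no other array contradicted it, and an interval when its averaged probe ratio changed over 1.6-fold on both arrays. How those ratios were normalised, and the build of the intervals in these tables, is not given in the sources used here. The array headers name mm9.

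For expression, median spot signals were used because the files hold no mean spot signal, background was corrected with limma's normexp (offset 50) and each array was normalised by loess in R 4.3.3 with limma 3.58.1. Control spots had weight 0 in loess and were left out after it, as were spots marked as outliers, while saturated spots were kept. Spots of 1 probe were averaged. Probes well above background on at least 2 arrays in the channel of one genotype were kept, which left 21309 probes with a symbol, and the brightest probe stood for its gene. Symbols came from the accession through a gene table of assembly GRCm38.p6 or, for 17 probes, only from the authors' deposited tables, and 16060 probes had none. That assembly served for names and for which genes neighbour Tlr2, and none of its coordinates are given.

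Genes were tested with lmFit and eBayes on the log2 ratios of the 4 expression arrays, with a dye effect as intercept and a sign per array, and Benjamini-Hochberg adjustment over 14701 genes at 0.05. Of 26 fixed gene lists, 24 had at least 5 measured members and were tested with camera (preset correlation 0.01), with an estimated correlation and fry as alternatives. The 24 lists are those named with their results in the report. The sex-linked list and the substrain marker Nnt were too short to test and are given as values. Genes near Tlr2 were to be tested among called genes. As limma called 0, hits by the submitters' rule were used instead, in a two-sided Fisher's exact test.

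For methylation, the processed intensity was taken as a log2 ratio and centred on each array's median, with no loess. Probes above background in at least 1 channel of each array were kept. The true SmaI intervals are known here only for the authors' deposited hits, so probes whose starts lay up to 500 bp apart were joined into an interval and averaged. The submitters' rule and limma on interval means were applied. With 2 arrays of the same dye orientation, limma's spread rests on 1 difference per interval and on the prior. No genome or annotation of mm9 was used here, so intervals were assigned to no gene, the overlap of methylation with expression was not analysed, and the named intervals follow the rule without its condition of an assigned gene. The test of intervals near Tlr2 was run for the whole of chromosome 3.

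Genes were named by a fixed rule, with Tlr2 first. It then takes up to 12 genes higher and 12 lower among those called in limma with the same direction on all 4 arrays, and, as too few were called, the largest mean changes among genes at least 1.6-fold the same way on all 4 arrays, given as values. Transcripts without a proper gene symbol were left out, and a few genes that the rule names are not reported here, although they stay in the counts and list tests. It adds up to 4 members of each list by smallest p, Nnt and the sex-linked genes always, and the 8 highest and 8 lowest intervals with at least 2 probes past the submitters' rule. Other genes named, among them the Hox genes, were chosen after their values were seen. The groups, tests, gene lists, naming rule and most alternatives were set before the data were examined, and the joining distance with its alternatives, single probes included, and the filter on both channels were chosen after.

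The procedures were tested on simulated data. Over 14701 genes on 4 simulated expression arrays, limma recovered 76% of 100 genes changed by 1 log2 unit and 98% of 100 changed by 2, with 10 false calls. Over 29875 simulated intervals on 2 arrays, the submitters' rule recovered 60% of 100 intervals changed by 1 log2 unit and limma 37%, both recovered 100% of 100 changed by 3, and there were 215 false rule hits and 3 false limma calls. The simulated intervals all had the same spread, and the noise of all simulated arrays was independent, which the real arrays need not follow. These shares therefore do not show that limma would call large changes in the real data. There Tlr2, at a mean log2 ratio of -4.86, had an adjusted p of 0.314. An interval on chromosome 3 at -5.66 had 0.378 in the fit over all intervals. Other background corrections, filters, thresholds, probe summaries and left-out arrays were tried as alternatives. Depth is not counted on arrays, and their number limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.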

Results

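Colonic mucosa of C57BL/6 mice lacking Tlr2, a cell-surface receptor for bacterial lipoproteins, was compared with mucosa of wild-type C57BL/6 mice at postnatal day 90. Transcript levels were measured on 4 two-colour expression arrays, each holding 1 knockout and 1 wild-type sample. DNA methylation was measured on 2 two-colour arrays by methylation-specific amplification, in which DNA is cut with SmaI and then XmaI, and a stronger signal marks an interval whose ends are methylated. Arrays are named here by the number of the knockout sample, so expression was measured for pairs 1, 2, 4 and 5 and methylation for pairs 1 and 4. The wild-type sample carried Cy5 on the expression arrays of pairs 1 and 2 and Cy3 on those of pairs 4 and 5. On both methylation arrays the wild-type sample carried Cy3, so a dye effect could not be separated from the genotype there. The sample codes differ between arrays, but no label says outright that each code is a separate animal, so a limma p-value measures the spread between these samples. The p-values of Fisher's exact test, the shuffles and the permutations instead take genes or intervals as independent units, and do not measure that spread. Genes of a list need not be independent, and the correlation estimated within the interferon list was 0.295.

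Each expression array held 43379 spots that were not controls. Between 63.3% and 76.5% of them were well above background in the wild-type channel and between 67.7% and 71.9% in the knockout channel. Of 41174 probes, 25114 had a gene symbol, and 14701 named genes were tested. Each methylation array held 103507 spots with a position, 93.55% of these spots passed the filter on both arrays, and the probes of the 95700 spots kept, without outliers, were joined into 29875 intervals. The small number of arrays limits the precision of every value below.

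Tlr2 transcript was strongly lower in the knockout channel of every expression array, with log2 ratios of knockout over wild type of -4.42, -5.31, -5.50 and -4.20 for pairs 1, 2, 4 and 5. The mean was -4.86 ± 0.643 (SD, n = 4), a 29.0-fold difference. The 10 spots of the 1 Tlr2 probe ranged from -5.67 to -3.99 over the arrays, and the probe remained well above background in both genotypes on 4 arrays. In the authors' deposited table the mean Tlr2 ratio was 0.0116. With a dye term in the model, limma gave Tlr2 an adjusted p of 0.314, and without it 0.0273.

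The first comparison asked which transcripts differ in the mucosa without Tlr2. Among genes at least 1.6-fold the same way on all 4 arrays, the lowest ratio beside Tlr2 was that of Aadac, an arylacetamide deacetylase of the endoplasmic reticulum, at -2.94 ± 0.0721 (log2, SD, n = 4), a 7.70-fold difference. Wdfy1, which encodes an endosomal FYVE-domain protein, was at 2.32 ± 0.249 on the probe used. Retnlb, a goblet cell protein secreted into the gut lumen, was at 2.15 ± 0.90. Mme, the membrane endopeptidase neprilysin, was at 1.67 ± 0.768, and Nnt, a mitochondrial transhydrogenase gene that carries a deletion in the C57BL/6J substrain, was at 1.16 ± 0.173, with its second probe at 1.24 ± 0.431. Nnt was fixed beforehand as a substrain marker. A difference of substrain between the knockout and wild-type mice was not tested, and it cannot be told apart from the loss of Tlr2 in any comparison here.

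Genes of the interferon response and of the circadian clock made up most of the other genes at least 1.6-fold higher on all 4 arrays. Ddx60 was at 1.86 ± 0.864, Oasl2 at 1.71 ± 0.73, Gbp3 at 1.45 ± 0.40, Ifit2 at 1.19 ± 0.312 and Rsad2 at 1.12 ± 0.282 (mean log2 ratio ± SD, n = 4). Of the clock genes, Ciart was at 1.47 ± 0.534, Per1 at 1.18 ± 0.231 and Dbp at 1.05 ± 0.372. Genes at least 1.6-fold lower on all 4 arrays, besides Tlr2 and Aadac, were Pdk4, a kinase that restrains pyruvate oxidation, at -1.90 ± 1.02, Abcg5, a sterol exporter, at -1.38 ± 0.464, Nfil3, a transcription factor that represses clock output genes, at -1.20 ± 0.594, and Ttc3 at -1.005 ± 0.0892. In total 13 genes were higher and 6 lower by this criterion.

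**Figure D1:**
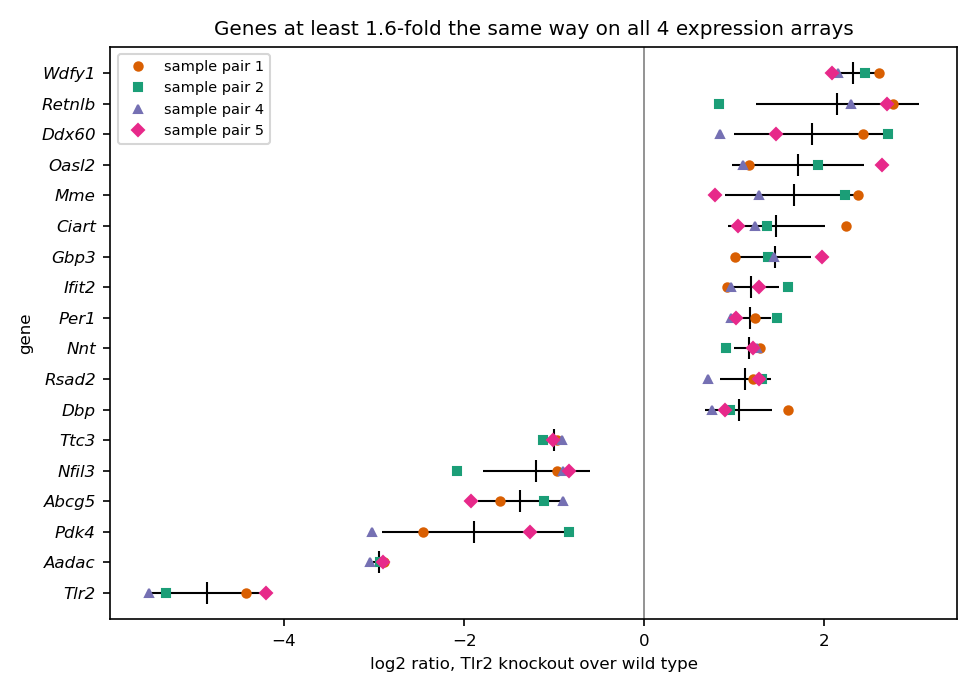
Log2 ratio of knockout over wild type (horizontal axis) for the genes named by rule that were at least 1.6-fold higher or lower on all 4 expression arrays (vertical axis). Symbols are the 4 sample pairs, the vertical tick is the mean and the bar is the SD. Tlr2 lies farthest to the left at a mean of -4.86, Aadac at -2.94, and Wdfy1 farthest to the right at 2.32.

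By limma with a dye term, 0 genes were higher and 0 lower at an adjusted p under 0.05. The smallest adjusted p was 0.0577, for Aadac, followed by 0.0772 for Wdfy1, and 1193 genes had an unadjusted p under 0.05 where 735.05 were expected by chance. Without the dye term limma called 3 genes, with Aadac lower at an adjusted p of 0.0033, Tlr2 lower at 0.0273 and Wdfy1 higher at 0.0273. By the submitters' rule, which asks for over 1.6-fold on at least 2 arrays with none contradicting, 112 genes were higher and 105 lower, and without pair 1 these counts were 388 and 495. With Agilent processed signals the rule gave 271 and 278, and limma then called 0 genes higher and 4 lower. The direction was the same on all 4 arrays for 15.6% of genes. Arrays of independent sign would give 12.5%. The arrays were not independent, with Pearson correlations from -0.42 to 0.57, so that share is no chance level for them.

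The probes of Wdfy1 differed in direction. Both probes for NM_001111279 were higher in the knockout, at 2.32 ± 0.249 and 2.33 ± 0.475 (log2, SD, n = 4), and the probe for NM_027057 was at -0.55 ± 0.0823. The authors' deposited table likewise lists NM_001111279 at a mean ratio of 5.66 and NM_027057 at 0.512. Of the 5116 genes with more than 1 probe kept, 0 had probes that passed the submitters' rule in opposite directions, since the lower Wdfy1 probe, negative on 4 arrays, did not pass it. Of the 2 probes for Per2, 1 was at 1.17 ± 0.429 and the other at -0.04 ± 0.115.

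Interferon-stimulated genes were higher as a group in the knockout mucosa by camera with a preset correlation (adjusted p of 2.18e-19), against an adjusted p = 0.785 with an estimated correlation, and fry gave 0.308. Of 37 measured members, 23 were positive on all 4 arrays, 16 passed the submitters' rule upward and 0 downward, and the mean log2 ratio was 0.64. The list median was 0.70, 0.65, 0.34 and 0.83 for pairs 1, 2, 4 and 5. Igtp, an immunity-related GTPase, was at 0.75 ± 0.107 (SD, n = 4), beside the values above for Gbp3, a guanylate-binding protein, Ifit2, which restricts viral translation, and Rsad2, the antiviral enzyme viperin. Adjusted over the list alone, 21 of 37 genes passed in limma, against 0 over all genes tested. The share of members passing the submitters' rule was larger than that of other genes by Fisher's exact test (adjusted p = 6.84e-19).

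Circadian clock genes were higher as a group, with members on both sides. Camera with a preset correlation gave an adjusted p of 4.9e-05, against an adjusted p = 0.785 with an estimated correlation, and fry gave 0.305. Of 18 measured, 6 passed the submitters' rule upward and 2 downward, and the mean log2 ratio was 0.35. Tef, a transcription factor of clock output, was at 0.95 ± 0.451 (SD, n = 4), and Per2, a repressor of the clock loop, at 1.17 ± 0.429 on 1 of its 2 probes. Nfil3 was at -1.20 ± 0.594. The list median was -0.07, 0.84, 0.45 and 0.46 for pairs 1, 2, 4 and 5. Adjusted over the list alone, 7 of 18 genes passed in limma, against 0 over all genes tested, and Fisher's exact test on rule hits gave an adjusted p of 9.17e-10.

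Genes of cholesterol and lipid synthesis were higher as a group, and those of PPAR signalling and fatty acid oxidation lower, by camera with a preset correlation (adjusted p of 2.99e-06 and 2.24e-05). Each had an adjusted p = 0.785 with an estimated correlation, and fry gave 0.627 and 0.557. Among 26 synthesis genes the mean log2 ratio was 0.38, with 4 passing the submitters' rule upward, and without pair 4 the mean was 0.25. Fasn, the fatty acid synthase, was at 0.71 ± 0.396 and Pmvk, a mevalonate pathway kinase, at 0.67 ± 0.258 (SD, n = 4). The list median was -0.17 for pair 1 and 0.48, 0.89 and 0.51 for pairs 2, 4 and 5. Among 26 oxidation genes the mean was -0.39, with 3 passing the rule downward. Angptl4, an inhibitor of lipoprotein lipase, was at -1.47 ± 1.19, Acot1, an acyl-CoA thioesterase, at -0.71 ± 0.773, Cpt2, which carries fatty acids into mitochondrial oxidation, at -0.60 ± 0.207, and Plin2, a lipid droplet coat protein, at -0.58 ± 0.176.

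Adjusted over the list alone, 2 of 26 synthesis genes and 4 of 26 oxidation genes passed in limma, against 0 over all genes tested. Without pair 1 the oxidation list no longer passed, with a mean of -0.45 and a camera adjusted p of 0.0505, and without pair 4 its mean was -0.24. Fisher's exact test on rule hits gave an adjusted p of 0.00321 for the synthesis list and 0.0257 for the oxidation list.

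Adipocyte markers were higher as a group, with large differences between the pairs. Camera with a preset correlation gave an adjusted p of 3.88e-05, against an adjusted p = 0.785 with an estimated correlation, and fry gave 0.692. The list median over 11 measured markers was -0.32, 0.12, 0.68 and 1.57 for pairs 1, 2, 4 and 5, and the mean log2 ratio was 0.57. The higher medians were those of pairs 4 and 5, where the knockout carried Cy5, and 0 markers were positive on all 4 arrays. Car3, a carbonic anhydrase abundant in fat, was at 1.09 ± 1.38, Adipoq, the hormone adiponectin, at 0.93 ± 1.49, Cfd, or adipsin, at 0.74 ± 1.72, and Plin1, which coats lipid droplets of fat cells, at 0.66 ± 0.938 (SD, n = 4). None of the markers passed the submitters' rule. Adjusted over the list alone, 0 of 11 markers passed in limma. Fisher's exact test on rule hits gave an adjusted p of 1. Without pair 5 the mean was 0.17, and without pair 1 it was 0.86.

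The 19 other lists did not pass camera. Among markers of other cell types, the adjusted p was 0.0511 for enteroendocrine cells (mean log2 ratio -0.23), 0.101 for goblet cells (0.21), 0.101 for T, NK and innate lymphoid cells (-0.24), 0.174 for enteric neurons and glia (0.13), 0.223 for B and plasma cells (-0.13), 0.243 for crypt stem and proliferating cells (-0.08), 0.476 for smooth muscle (-0.12), 0.708 for macrophages, dendritic cells and granulocytes (-0.05), 0.708 for absorptive colonocytes (-0.02), 0.726 for fibroblasts and extracellular matrix (-0.0050), 0.881 for erythrocytes (-0.07) and 0.993 for endothelium (-0.0093). For the remaining lists it was 0.392 for MHC class II and antigen presentation (-0.13), 0.476 for antimicrobial and epithelial defence (-0.10), 0.476 for tight junctions and epithelial adhesion (0.03), 0.708 for the TLR family and its adaptors (-0.04), 0.708 for NF-kB and inflammatory targets (-0.07), 0.708 for xenobiotic metabolism (0.02) and 0.726 for the DNA methylation machinery (0.02). Fisher's exact test on rule hits passed for 2 of these 19 lists, with an adjusted p of 0.00262 for antimicrobial and epithelial defence, where 2 members were higher and 2 lower, and of 0.0257 for T, NK and innate lymphoid cells, where 0 were higher and 3 lower. Adjusted over the list alone, 0 members of each of these lists passed in limma. The mean and the camera direction differed in sign for absorptive colonocytes and fibroblasts, whose medians were 0.03 and 0.04. For the DNA methylation machinery the median, -0.01, differed in sign from the mean.

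**Figure D2:**
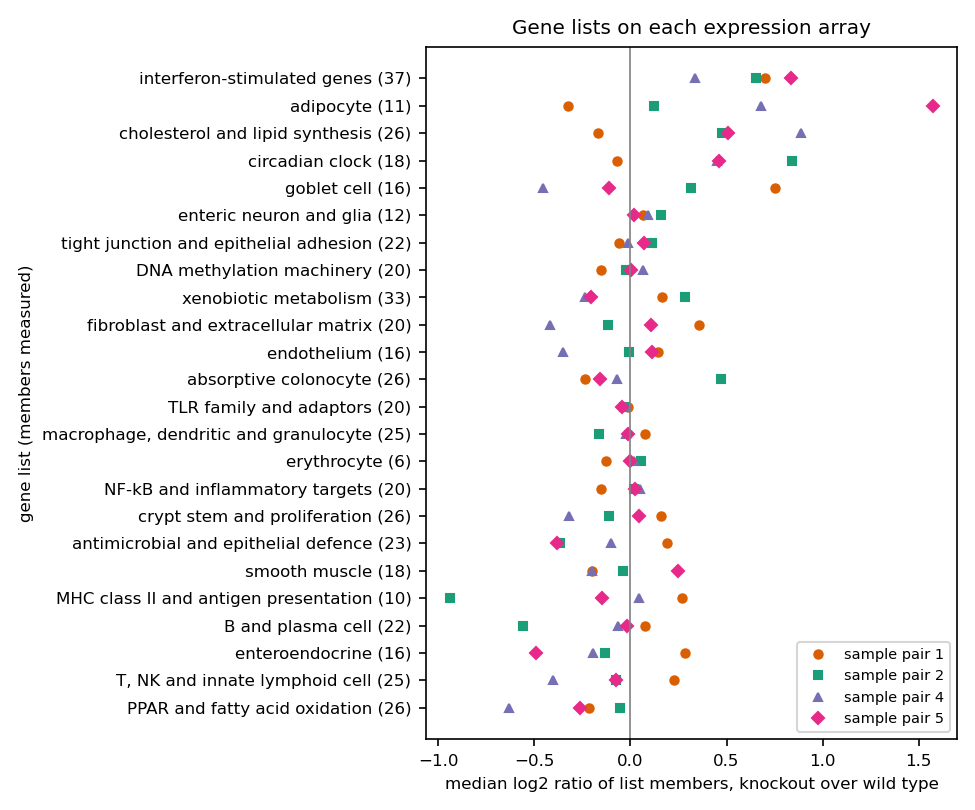
Median log2 ratio of knockout over wild type (horizontal axis) of each gene list (vertical axis, number of measured members in brackets), with 1 symbol per sample pair. The interferon list lies between 0.34 and 0.83 on all 4 arrays, while the adipocyte list runs from -0.32 for pair 1 to 1.57 for pair 5.

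Several members of these lists had large mean ratios with a wide spread. Reg3g and Reg3b, antimicrobial lectins of the epithelium, were at -1.96 ± 1.67 and -1.85 ± 1.58 (log2, SD, n = 4), with Reg3b saturated on 2 arrays. Duoxa2, the maturation factor of a hydrogen peroxide-producing oxidase, was at 1.16 ± 0.79. Gzma and Gzmb, granzymes of cytotoxic lymphocytes, were at -1.46 ± 0.797 and -0.96 ± 0.618, and the chemokine Ccl5 at -1.30 ± 0.94. Cldn8, a sealing claudin of tight junctions, was at -0.95 ± 0.837, Anpep, a brush border aminopeptidase, at -1.48 ± 1.27, and Cyp3a44, a cytochrome P450, at -1.10 ± 0.493. None of these genes passed limma over all genes tested. Signals were saturated in at least 1 channel on all 4 arrays for 6 of 16 goblet cell genes, 5 of 26 absorptive genes, 3 of 23 antimicrobial genes and 4 of 22 tight junction genes, so the ratios of those genes carry no reliable size.

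The arrays did not share 1 overall direction. Across 14690 genes, which are not independent replicates, the Pearson correlation of log ratios was 0.55 between pairs 2 and 4, 0.42 between pairs 2 and 5 and 0.57 between pairs 4 and 5. Pair 1 correlated at -0.21 with pair 2, -0.42 with pair 4 and -0.10 with pair 5. Tlr2 was lower in the knockout channel of pair 1 as on the other arrays. All 4 expression arrays lay on 1 slide, and both methylation arrays on another, so no slide could be tested as a batch. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were at 0.30 ± 0.488, -0.30 ± 0.492, 0.12 ± 0.124 and 0.14 ± 0.316 (log2, SD, n = 4).

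The Hox genes, transcription factors whose paralog groups mark position along the body axis, were looked at after their values were seen. For pair 1, Hoxd13 was at -4.76 and Hoxd4 at 3.09, whereas for pair 4 Hoxd13 was at 2.15 and Hoxd4 at -1.82 (log2). The median of paralog groups 10 to 13 was -1.48, 0.50, 1.21 and 0.50 for pairs 1, 2, 4 and 5, and that of groups 1 to 9 was 0.71, -0.21, -0.33 and 0.08. Over 29 Hox genes, the Spearman correlation of log ratio with paralog group was -0.57 for pair 1 (permutation p = 0.0013, adjusted p = 0.0052), 0.28 for pair 2 (adjusted p = 0.135), 0.49 for pair 4 (adjusted p = 0.0162) and 0.29 for pair 5 (adjusted p = 0.135), over 4 such tests by permutation.

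**Figure D3:**
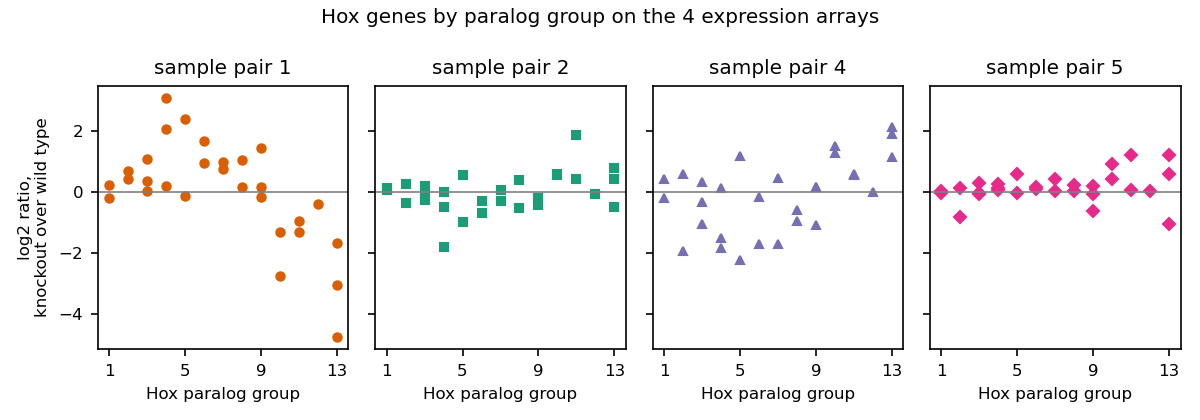
Log2 ratio of knockout over wild type (vertical axis) of 29 Hox genes by paralog group (horizontal axis), with 1 panel per sample pair. Groups 10 to 13 lie low for pair 1, with a median of -1.48, and high for pair 4, with a median of 1.21.

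A further comparison asked whether genes near Tlr2 on chromosome 3 held more differences than other genes, because a knockout allele can carry a flanking segment from the strain it was made in. Of 165 genes within 10 Mb, Tlr2 itself left out, 6 passed the submitters' rule. Mnd1, a meiotic recombination gene, was at 0.78 ± 0.141 and Pmvk at 0.67 ± 0.258 (log2, SD, n = 4), followed by Sprr2h at 0.65 ± 0.283 and Rhbg, an ammonium transporter, at 0.57 ± 0.238. Sprr2k and Sprr2e, small proline-rich proteins of the cornified envelope that are near copies and could share probe signal, were at -0.86 ± 0.41 and -0.54 ± 0.362. Elsewhere 208 of 14532 genes passed, an odds ratio of 2.60 (95% interval 0.929 to 5.88, two-sided Fisher's exact p = 0.0338). The test no longer passed without pair 4 (1.97, Fisher's exact p = 0.155), without pair 5 (2.09, p = 0.134), without background correction (1.98, p = 0.191), with the strict filter (2.27, p = 0.0787) or with the mean of all probes (2.45, p = 0.0609). Within 5 Mb the odds ratio was 1.81 (Fisher's exact p = 0.309) and within 20 Mb 1.60 (Fisher's exact p = 0.22). By the criterion of at least 1.6-fold the same way on all 4 arrays, 0 of 77 genes passed within 5 Mb, 0 of 165 within 10 Mb (Fisher's exact p = 1) and 1 of 306 within 20 Mb (Fisher's exact p = 0.315). On the whole of chromosome 3, 4 of 696 genes passed it, namely Aadac, Mme, Gbp3 and Ciart, against 14 of 14001 elsewhere. The odds ratio was 5.77 (95% interval 1.38 to 18.4, Fisher's exact p = 0.00897), in a test chosen after the values were seen. By the submitters' rule the whole chromosome held 17 of 696 against 197 of 14001 elsewhere. That odds ratio was 1.75 (95% interval 0.996 to 2.90, Fisher's exact p = 0.0338), and its interval overlaps that of the 5.77.

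The authors' deposited tables of expression list 328 transcripts as increased and 277 as decreased. Of the genes in them that were tested here, 224 of 225 and 188 of 190 had a mean ratio in the same direction, and 79 and 83 passed the same limits on the ratios computed here. The ratios themselves differ in size, so these limits are not equally strict on both. Mme was 3.17-fold higher here against an authors' mean ratio of 8.27, while Reg3g was 3.89-fold lower against 0.361. On single arrays the authors' ratios ran from 4.24 to 13.2 for Mme and from 0.0576 to 0.766 for Reg3g. The fold here rests on the mean log2 ratio, and the authors' mean on linear ratios. For Reg3g, with its wide spread, these means therefore do not show a difference in size. With Agilent processed signals in place of normexp, the rule gave 271 higher and 278 lower genes here. The rule passed 33 higher and 22 lower genes that these tables do not list.

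The second comparison asked where DNA methylation differs in the same mucosa, and most of the intervals with the largest differences lay on chromosome 3. Positions follow the build named in the array headers, mm9, and the genes at them are not given because no annotation of that build was used here. Among intervals with at least 2 probes that passed the submitters' rule, the lowest methylation signal relative to wild type was at chromosome 3, 78920958 to 78921505, at -5.66 ± 0.162 (log2, SD, n = 2), a 50.7-fold difference over 3 probes. Next came 69708728 to 69709608 on the same chromosome at -4.94 ± 0.0985, a 30.8-fold difference over 4 probes. Also on chromosome 3 were 73478938 to 73479324 at -3.79 ± 0.234, 82891855 to 82892366 at -3.77 ± 0.273 and 83705009 to 83705427 at -3.71 ± 0.27. The highest signal of the knockout relative to wild type was on chromosome 3 as well, at 84232805 to 84233125, at 3.43 ± 0.265. Every probe of these intervals was above background in both genotypes on both arrays.

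Outside chromosome 3, the lowest of these intervals were on chromosome 9, 44950614 to 44951162, at -4.26 ± 0.36, on chromosome 5, 146267158 to 146267272, at -3.91 ± 0.243, and on chromosome 2, 146047194 to 146047395, at -2.24 ± 0.482 (log2, SD, n = 2). The highest was on chromosome 7, 74614890 to 74615951, at 2.18 ± 0.365. The other 6 highest intervals were on chromosomes 2, 12, 1, 13, 19 and 1 and had means between 1.69 and 1.92. In these 6 at most 50% of the probes were above background in the wild-type channel. The adjusted p of the 16 named intervals lay between 0.378 and 0.653 in limma over all 29875 intervals, of which 9865 had 1 probe. Over only the intervals with at least 2 probes, from which these were named, limma called 1 higher and 7 lower. Which intervals those were is not given here.

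Intervals with at least 2 probes that differed over 4-fold the same way on both arrays were concentrated on chromosome 3. It held 6 of 780 such intervals against 2 of 19230 on other chromosomes, an odds ratio of 74.3 (95% interval 13.3 to 742, two-sided Fisher's exact p = 9.01e-08). All 6 lay within 14.5 Mb, between 69708728 and 84232805, with 5 lower and 1 higher. In 1000 shuffles of the intervals the fullest window of 20 Mb held at most 3, so that the permutation p was 0.001, the smallest that these shuffles can give. The 4-fold limit and the window were chosen after the values were seen. Over intervals that passed the submitters' rule the difference was far smaller, with 67 of 1183 on chromosome 3 against 1017 of 28692 elsewhere (odds ratio 1.63, Fisher's exact p = 0.000333), and, with at least 2 probes, 21 of 780 against 282 of 19230 (odds ratio 1.86, Fisher's exact p = 0.0103).

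**Figure D4:**
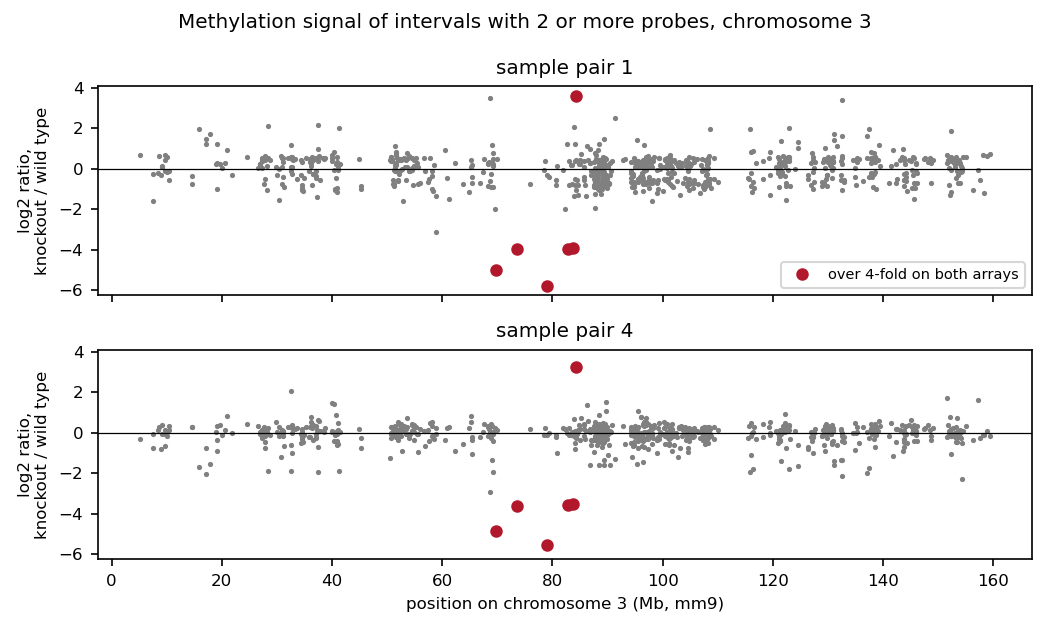
Log2 ratio of methylation signal, knockout over wild type (vertical axis), of intervals with 2 or more probes along chromosome 3 in Mb of mm9 (horizontal axis), with 1 panel per sample pair. Larger filled circles are the 6 intervals over 4-fold on both arrays, which lie between 69708728 and 84232805, 5 below 0 and 1 above.

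By the submitters' rule, over 1.6-fold on both arrays, 598 intervals were higher and 486 lower in the knockout. If the arrays were independent, 140.7 higher and 675.8 lower were expected, and 1238 intervals were higher for pair 1 and lower for pair 4 where 419.2 were expected. Limma called 0 intervals higher and 0 lower, with a smallest adjusted p of 0.378 and 1437 intervals at an unadjusted p under 0.05, where 1493.8 were expected. The Pearson correlation between the arrays was 0.0445 across intervals and the Spearman correlation 0.145, and intervals are not independent replicates. With at least 2 probes, 87 intervals were higher and 216 lower, and limma called 1 higher and 7 lower. After loess the rule gave 745 higher and 308 lower and limma 159 and 28. After normexp the rule gave 109 higher and 1883 lower and limma 18 and 597, and the Pearson correlation of the arrays was 0.37.

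Intervals that passed the rule upward were dim. Their median log2 brightness was 4.16, against 11.73 for all intervals (quartiles 9.26 and 13.02) and 7.85 for those that passed downward. After normexp it was 13.2 for the higher and 4.42 for the lower intervals. With both channels above background on both arrays, 168 intervals were higher and 458 lower. The authors' deposited tables list 141 intervals as increased and 246 as decreased, and of those that could be recomputed, 138 of 140 and 241 of 244 had the same direction here, while 79 and 194 passed the rule.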

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

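The use of a test or value to weigh an explanation in this part was chosen after the result was seen, although the array correlations themselves were planned. Among 130 gene and list values with 4 pairs each, 10 had 1 pair far from the others by Dixon's test at 0.829, and chance alone sets apart about 1 in 20 such groups. For pair 1, the neuropeptide gene Sst was at 0.47 (log2, the others between -0.74 and -0.58), the replication factor Mcm2 at -0.63 (others -0.31 to -0.26), the plasma cell and epithelial proteoglycan Sdc1 at -0.51 (others 0.62 to 0.64) and the median of the NF-kB and inflammatory list at -0.155 (others 0.02 to 0.05). For pair 2, Nfil3 was at -2.08 (others -0.97 to -0.83). For pair 4, Rsad2 was at 0.70 (others 1.21 to 1.30), the lipopolysaccharide co-receptor Cd14 at 0.052 (others -0.74 to -0.64), the serotonin synthesis gene Tph1 at -1.51 (others -0.52 to -0.41), the aldo-keto reductase Akr1b8 at -0.95 (others -0.42 to -0.32) and the Y-linked Eif2s3y at 1.03 (others -0.02 to 0.12).

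The expression array of pair 1 ran against the other 3. An exchange of the genotype labels on that array is argued against by Tlr2, which was at -4.42 there, and a dye bias common to all 4 arrays by the correlation of Cy5 over Cy3 of pair 2 with pairs 1, 4 and 5, which was -0.21, -0.55 and -0.42. A dye bias on the arrays of pairs 1, 4 and 5 stays open, since their Cy5 over Cy3 correlated at 0.42 (pairs 1 and 4), 0.10 (1 and 5) and 0.57 (4 and 5), signs that the pattern itself sets. For the hypothesis that the tissue in pair 1 came from different positions along the colon, the log ratios of 29 Hox genes followed the paralog group at a Spearman correlation of -0.57 for pair 1 and at 0.28, 0.49 and 0.29 for pairs 2, 4 and 5, but these genes were chosen after their values were seen, so they raise this explanation without testing it. The position of each sample along the colon is not given in the sources used here, and a difference between the samples themselves was not tested.

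With 4 arrays, each exchange of genotype on some of them makes 1 of 8 sign patterns, too few for a share under 0.05. By the submitters' rule the real pattern gave 217 genes, 2 of 8 patterns gave as many, and the highest other gave 986. That pattern exchanges pairs 2, 4 and 5 against pair 1, and its count points to a structure of the samples in which pair 1 opposes the rest. The dye-term model was fitted for 7 patterns, also too few. Limma called 0 genes in the real pattern and at most 0 in the others, so 7 of 7 gave as many. Camera called 5 lists in the real pattern and at most 9 in another, and 6 of 7 gave as many. The interferon list had a camera adjusted p of 2.18e-19 in the real pattern and 1.55e-20 with the genotype of pair 4 exchanged.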

How the results depend on the processing

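Alternatives on the joining of probes (200 bp, 1000 bp or single probes) and on both methylation channels above background were chosen after seeing the data, and the others were planned. Of 1199 values of named genes under 11 alternatives, 30 moved by more than 1 SD. The mean changed sign in 2, Alas2 without pair 1 and Kdm5d without pair 4, and in 0 values of genes that passed the submitters' rule. Among 311 values of single lists, 20 passed the threshold only under an alternative and 11 no longer passed. Of 131 counts and other main values, 78 stayed on their side of the threshold, within 1.5 times or, for correlations, within the spread of the main value, and the others follow. The cause was not tested, except where fewer arrays, fewer probes or a stricter limit are the alternative itself.

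For expression, limma called 4 genes lower with Agilent processed signals, 1 lower without background correction, 1 lower with all 4 arrays above background in both channels, 1 higher and 2 lower with no dye term, and 1 higher and 1 lower at an adjusted p under 0.10. The submitters' rule gave 271 higher and 278 lower with processed signals, 40 and 38 at 2.0-fold, and 13 and 6 on all 4 arrays. Leaving out 1 pair in turn gave 93 to 388 higher and 84 to 495 lower, with the most without pair 1, and 7 to 9 lists by camera. With an estimated correlation 0 lists passed, and the interferon, adipocyte, clock, PPAR and cholesterol lists each had an adjusted p of 0.785. Fry called 0 lists, with adjusted p of 0.308, 0.692, 0.305, 0.557 and 0.627 in that order. The mean correlation of the expression arrays, 0.135, was 0.514 without pair 1 and 0.015, 0.0372 and -0.0265 without pairs 2, 4 and 5, moves smaller than the SD over the pairs of arrays. The mean of the cholesterol list ran from 0.25 to 0.57 when 1 pair was left out and that of the adipocyte list from 0.17 to 0.86. The mean of the PPAR list ran from -0.48 to -0.24 when 1 pair was left out, and without pair 1 it was -0.45 with an adjusted p of 0.0505. The odds ratio near Tlr2 was 1.98 without background correction (Fisher's exact p = 0.191), 2.27 with the strict filter (0.0787), 2.45 with the mean of all probes (0.0609), 1.81 within 5 Mb and 1.60 within 20 Mb. Leaving out 1 pair in turn it ran from 1.94 to 3.17 and no longer passed without pair 4 (1.97) or pair 5 (2.09).

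For methylation, the submitters' rule gave 109 higher and 1883 lower intervals with normexp, 87 and 216 with 2 or more probes, 376 and 143 at 2.0-fold, and 981 and 1743 for single probes. It gave 308 lower after loess, 1705 lower with no filter on dim probes, 1180 lower with probes joined up to 200 bp, 308 lower up to 1000 bp, and 168 higher with both channels above background. On 1 array alone, 1286 to 3269 were higher and 3831 to 5270 lower, as values with no test. Limma called 18 higher and 597 lower with normexp, 159 and 28 after loess, and 1 and 7 with 2 or more probes. The correlation of the arrays was 0.37 with normexp, 0.0849 after loess and 0.145 by Spearman. Saturation limits the ratios of some goblet, absorptive, antimicrobial and tight junction genes, and low signal those of dim methylation probes. No paired analysis was possible because each ratio already sets 1 knockout against 1 wild-type sample on the same array, which leaves no further block to fit. The overlap of methylation with expression and its alternatives were not run, for want of an annotation of the arrays' build, nor was limma on a single methylation array.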

Other observations

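All tests of an explanation in this part were chosen after the result was seen. Several cell type markers had opposite signs in pair 1 and the other pairs. Scnn1g, a subunit of the epithelial sodium channel, was at -3.28 for pair 1 and at 1.48, 1.88 and 0.69 for pairs 2, 4 and 5 (log2, knockout over wild type). Cd3d, a subunit of the T cell receptor complex, was at 1.18 against -0.97, -1.51 and -0.58, and Klrd1, a receptor of NK cells, at 0.69 against -0.66, -1.28 and -0.59. These genes were picked for their values, and none passed limma over all genes tested.

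Of the 18 clock genes, 6 were positive and 2 negative on all 4 arrays, the latter being Nfil3 and Arntl, which encodes the activator BMAL1. Arntl was at -0.98 ± 0.882 (mean log2 ratio, SD, n = 4), with -2.22, -0.62, -0.17 and -0.93 for pairs 1, 2, 4 and 5, and Nr1d2, a repressor of Arntl, at 0.75 ± 0.152. Adjusted over the list alone, the limma adjusted p was 0.0056 for Nr1d2, 0.0119 for Nfil3 and 0.0744 for Arntl, which did not pass. These members were picked for their values, and activators and repressors were not compared by a test. The hour at which the tissue was taken is not given in the sources used here.

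The large methylation differences close together on chromosome 3 were weighed against noise, dye and strain. For noise of single probes, the 6 intervals on chromosome 3 whose first probe alone was over 4-fold on both arrays were examined. The mean of their other probes followed past 1.6-fold on both arrays in 6 (exact 95% interval of the share 0.541 to 1), against 5 of 10 on other chromosomes. All 6 belong to the large intervals for which chromosome 3 was singled out, by the mean of all their probes. The share therefore largely restates that choice and does not settle whether noise of single probes played a part. After loess 6 of the intervals stayed over 4-fold, so a smooth trend of dye ratio with brightness does not account for their size. Loess could hardly bring intervals this far past 4-fold under that limit, and it removes no dye effect particular to single probes. Such an effect cannot be told apart from genotype with 1 dye orientation. A chromosome segment from another strain around the targeted gene is a candidate explanation that stays open, since the odds ratio of expression hits within 10 Mb of Tlr2 was 2.60 with a 95% interval of 0.929 to 5.88, was 1.81 within 5 Mb (Fisher's exact p = 0.309) and 1.60 within 20 Mb (Fisher's exact p = 0.22), and no longer passed without pair 4 (1.97) or pair 5 (2.09). Over the whole of chromosome 3, 4 of 696 genes were at least 1.6-fold the same way on all 4 arrays, against 14 of 14001 elsewhere. The odds ratio was 5.77 (95% interval 1.38 to 18.4, Fisher's exact p = 0.00897), in a test chosen after the values were seen. Where Tlr2 lies relative to the large methylation differences is not given, because no annotation of mm9 was used. A sequence difference at the enzymes' sites and a methylation difference cannot be told apart here, because no strain sequence was used, and an effect of Tlr2 itself on methylation there was not tested.

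Methylation intervals that passed the submitters' rule lay among dim probes. A smooth trend of dye ratio with brightness as the whole cause is argued against for the higher ones, since 745 passed after loess with a median log2 brightness of 4.13, against 598 before. Such a trend stays open for the lower ones, where 308 passed after loess, with a median of 7.54, against 486 before, with 7.85. Loess does not test how the background of dim spots is handled. With both channels above background on both arrays only 168 were higher, so an effect of background stays open for the higher ones. Noise of dim spots is a candidate explanation for part of the higher ones, since arrays independent of each other within 20 classes of brightness would give 452.7 of them and 565.2 lower ones, but it is not settled, because 598 lay above the 498 of the highest of 1000 shuffles within classes while intervals higher for pair 1 and lower for pair 4 were also in excess, at 1238 against 948.1. The arrays correlated at 0.0243 over the 7469 dimmest intervals and at 0.364 over the 7469 brightest. After normexp the 109 higher intervals were bright, with a median log2 brightness of 13.2, and the 1883 lower ones dim, at 4.42, and a biological explanation was not tested.

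In the authors' deposited tables the increased intervals were short, with a median of 171 bp and 54.6% of them up to 200 bp, and the decreased ones long, with a median of 1234.5 bp and 0.407% up to 200 bp (Fisher's exact p = 1.73e-40). Their median log2 brightness here was 13.36 and 8.25. After loess 51 of the increased and 117 of the decreased ones passed the rule here, against 79 and 194 before. Of the intervals joined here that passed the rule, 62 of 598 higher and 160 of 486 lower overlapped an interval of those tables with the same direction. On chromosome 3, the authors' deposited table also lists 79371261 to 79371544 as decreased, with ratios of 0.0597 and 0.0944 on the 2 arrays, and 83147070 to 83148511, with 0.173 and 0.198, each covered here by 1 probe. Off chromosome 3, the authors list chromosome 8, 49076048 to 49076797, as increased, with ratios of 18.8 and 13.2. That is above the 11.35 and 9.04 they list for chromosome 3, 84232070 to 84233864. Recomputed here over 4 probes, the chromosome 8 interval was at only 1.51 and 1.55 (log2) for pairs 1 and 4.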
